A study of Drosophila melanogaster with 36 samples.

How the data were processed

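The series holds 36 RNA-seq libraries of fly heads and thoraxes from 6 RNAi genotypes, with 3 libraries per tissue and genotype. GFP RNAi and white RNAi serve as the 2 controls, and the other 4 genotypes carry RNAi against Prosbeta5, ND-75, Tm1 or TER94. Per the labels' protocols, RNA was extracted with trizol and polyadenylated RNA was sequenced. The labels name no driver, sex or age of the flies. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these samples.

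The deposited values are whole read counts per gene, with 1 value for each of 15081 genes in each library. Per the submitters' processing notes, BWA, STAR and HTSeq were used with the dm3 genome build, and their versions are not given in the sources used here. No normalisation is recorded, and the values hold no entry for unassigned reads. The counting rule for reads that match several genes and the strand setting are not stated, so members of near-identical gene families are read as uncertain. Genes were identified by the identifiers in the deposited counts, and 14418 of them carry a current symbol. Gene names below are those of the deposited counts, so that the ND-75 gene appears as ND75.

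Everything after the counts was computed here. Each tissue was fitted separately on its 18 libraries with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the default expression filter, and the quasi-likelihood F-test with robust dispersion. Each RNAi group was compared with the mean of the GFP RNAi and white RNAi groups, so every contrast rests on 3 RNAi and 6 control libraries. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The filter left 11309 genes in the thorax and 11338 in the head. A joint fit of the 12 groups on 11967 genes tested whether the head response differed from the thorax response of the same RNAi. CPM values, which are counts relative to library size, are scaled by the TMM factors and given as mean ± SD over libraries, and log2 fold changes are given ± standard error. Fold changes of genes with 3 or fewer control counts are given as ratios with 95% exact counting intervals.

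Lists of genes of known function, 31 in number, were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and all alternatives except those said to be chosen later. The mitochondrially encoded transcripts matched 0 genes of the table, which leaves 30 lists and 240 list tests over the 8 comparisons of RNAi with controls. Each list was tested with fry from limma 3.58.1, with Benjamini-Hochberg adjustment over the 240 tests. Its directional p asks whether the members moved, on balance, one way, and its mixed p whether they changed in either direction. Neither compares a list with other genes. The camera test, which does make that comparison, was run with an estimated inter-gene correlation. Counts of changed members are given from the adjustment over all genes, and beside it from the adjustment over the list alone. Another 3 short lists, for gut identity, indirect flight muscle and the corpora cardiaca, were added after the data were seen.

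Named genes follow a rule. They are the targeted genes, the 6 genes with the highest and the 6 with the lowest fold change in each comparison, up to 4 members with the smallest adjusted p of each list described, up to 12 genes per tissue that changed in all 4 RNAi groups, w in the white RNAi groups, and Amyrel and ImpL2. The 6 highest and 6 lowest had to be called against the pooled controls and against each control group, with a mean log2 CPM of at least 1 over the tissue and no overlap between RNAi and control libraries. Any gene named outside this rule is said to have been chosen after its values were seen.

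The libraries hold between 28.9e6 and 52.4e6 counts. On simulated counts with the means, depths and spread of these libraries, in which 50 genes each were changed by 1.25-, 1.5-, 2- and 4-fold, the thorax comparisons recovered 40 to 48% of the genes changed 1.25-fold, 66 to 90% at 1.5-fold, 88 to 92% at 2-fold and 92 to 100% at 4-fold. The head comparisons recovered 48 to 56%, 82 to 92%, 92 to 98% and 100%. The tests of the difference between tissues recovered 20 to 28%, 71.4 to 80%, 83.7 to 94% and 96 to 100%. Between 4 and 10 of 158 to 163 thorax calls, and between 10 and 17 of 177 to 189 head calls, were unchanged genes. The changed genes were drawn from genes at 1 CPM or more in the controls, and the 2 controls were given the same means. These rates therefore do not cover genes near absent in the controls, or data with as many changed genes as here. Intervals and floors cover counting error only.

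Alternatives were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, no expression filter, a fit on the compared libraries alone, GFP RNAi or white RNAi alone as the control, the replicate number as a block, and leaving out each library in turn. For list tests, camera, the single controls and the replicate block were used. No list median changed sign with DESeq2 size factors, under which fry called 140 lists against 144 with TMM. Shared controls were handled by simulating unchanged groups against the same control libraries and by splitting the controls into GFP RNAi and white RNAi. Other splits of the samples were drawn, at most 100 per result. A further pair of alternatives was chosen after seeing the data: thorax TER94 RNAi replicates 2 and 3 summed as 1 library, and head tests without genes under 1 CPM in the control heads.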

Results

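Gene expression was measured by RNA-seq in heads and in thoraxes of flies with RNAi against 1 of 4 genes, and of flies with GFP RNAi or white RNAi as controls. The title of the series places the perturbation in skeletal muscle, of which the thorax holds the flight and leg muscles. Each of the 12 combinations of tissue and genotype has 3 libraries. The thorax libraries hold 28.9e6 to 39.0e6 counts and the head libraries 31.8e6 to 52.4e6. Prosbeta5 encodes a catalytic subunit of the proteasome, ND-75 a subunit of mitochondrial complex I, Tm1 a tropomyosin of the thin filament, and TER94 the fly homologue of the ATPase VCP (p97). Unless a sentence says otherwise, log2 fold changes compare 3 RNAi libraries with 6 control libraries, adjusted p-values are those of edgeR's quasi-likelihood test, and CPM are counts scaled by library size.

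The targeted genes were examined first, in every library. In the thorax, Prosbeta5 RNAi libraries held 65.4 to 72.0 CPM of Prosbeta5 against 134 to 156 in the controls, a log2 fold change of -1.06 ± 0.06 (adjusted p = 1.1e-08). ND75 stood at 167 to 179 CPM in ND-75 RNAi thoraxes against 955 to 1180 in the controls (-2.57 ± 0.09, adjusted p = 1.4e-11). TER94 stood at 234 to 235 CPM in TER94 RNAi thoraxes against 320 to 394 (-0.61 ± 0.06, adjusted p = 5.8e-07). Tm1 was not lower in the thoraxes labelled Tm1 RNAi, with 774 to 811 CPM against 716 to 868 in the controls (0.06 ± 0.06, adjusted p = 0.37), and without GFP RNAi replicate 3 the log2 fold change was 0.13, with an adjusted p of 0.023. The titles of these libraries read Tropo, and because Tm1 was not lower they are called the libraries labelled Tm1 RNAi. In the head, ND75 was lower in ND-75 RNAi (-0.34 ± 0.04, adjusted p = 4.7e-06) and Tm1 was higher in the heads labelled Tm1 RNAi (0.41 ± 0.05, adjusted p = 9.5e-06), at 334 to 399 CPM against 247 to 287. Tm1 was also higher in the heads of Prosbeta5 (0.44 ± 0.05), ND-75 (0.65 ± 0.05) and TER94 RNAi (0.17 ± 0.06). Prosbeta5 (-0.14 ± 0.10, adjusted p = 0.3) and TER94 (-0.10 ± 0.04, adjusted p = 0.089) passed no threshold in the heads of their own RNAi groups, although TER94 did in a fit on the 9 compared libraries (-0.12, adjusted p = 0.018). The pigment transporter gene w was not lower in the white RNAi controls. Its level was 1.66 to 1.89 CPM in white RNAi thoraxes against 1.52 to 1.57 with GFP RNAi, and 14.8 or more against 13.8 or less in the heads.

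**Figure D1:**
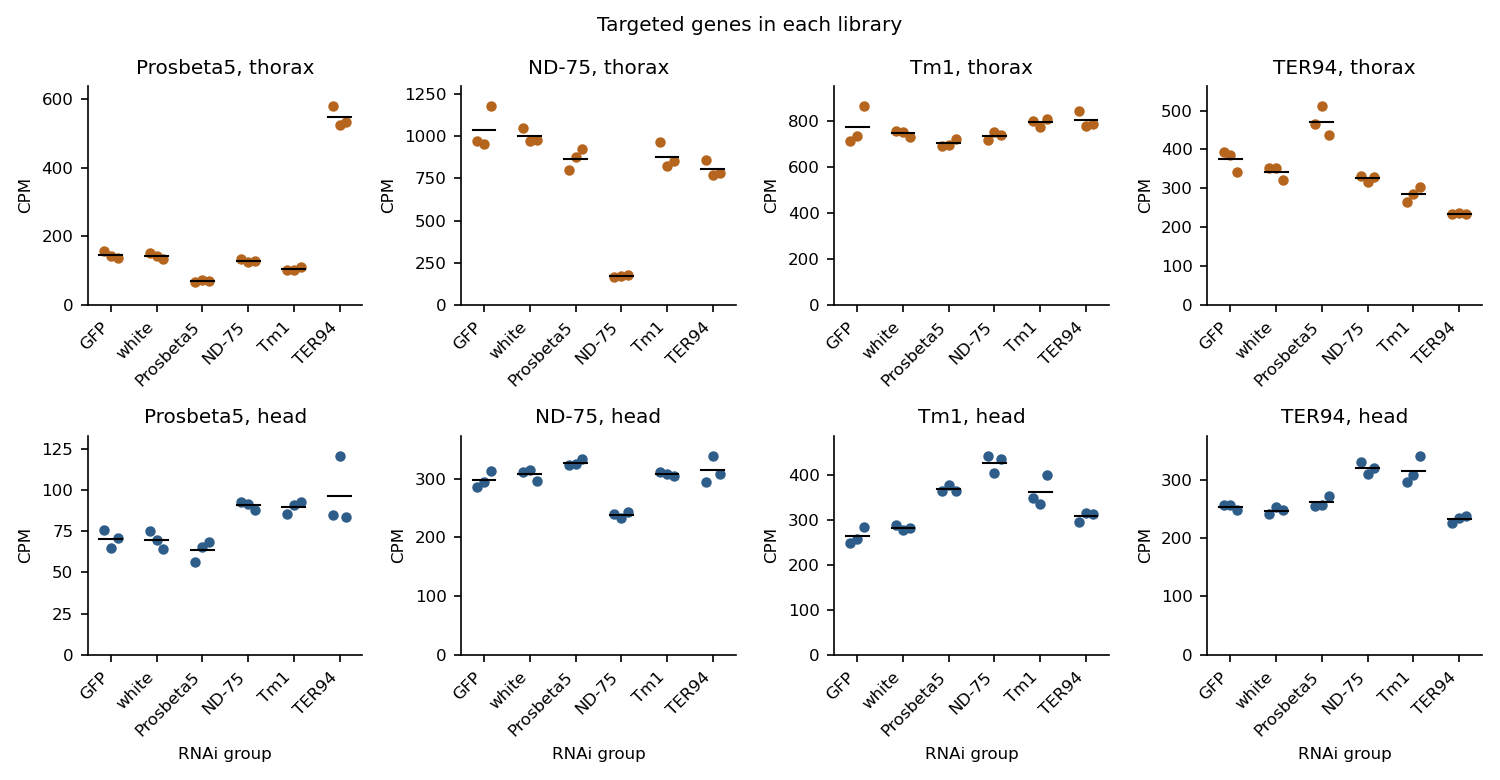
Each panel plots the CPM of 1 targeted gene in each of the 18 libraries of a tissue, grouped by RNAi genotype, with points for libraries and lines for group means, on an axis that starts at 0. ND75 falls from 955 to 1180 CPM in the control thoraxes to 167 to 179 in ND-75 RNAi, whereas Tm1 stays at 774 to 811 CPM in the thoraxes labelled Tm1 RNAi.

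How far the 2 control genotypes differ from each other sets the background of every comparison. In the thorax, 1409 of 11309 genes differed between GFP RNAi and white RNAi, 688 higher and 721 lower in GFP RNAi, and the count fell to 781 without white RNAi replicate 2 and to 868 without white RNAi replicate 3. The following genes were chosen after their values were seen. CG11313, a gene of the serine protease family, stood at 0.165 ± 0.0532 CPM with GFP RNAi and 61.2 ± 1.97 with white RNAi (log2 fold change -8.50, adjusted p = 1.6e-14). CG7900 stood at 2.72 ± 0.326 against 46.7 ± 2.05 (-4.10, adjusted p = 2.5e-14), and CG31832 at 25.2 ± 7.12 against 4.07 ± 1.11 (2.63, adjusted p = 2.2e-06). The cuticle pigment gene y was at 21.9 CPM or more in the GFP RNAi thoraxes and at 0.199 or less in the white RNAi thoraxes.

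The first thorax comparison asks which genes change when RNAi targets the proteasome subunit Prosbeta5. In Prosbeta5 RNAi thoraxes, 1806 genes rose and 1608 fell, 426 and 211 of them by at least 2-fold. Of 34 proteasome subunits, 31 rose and 1, Prosbeta5 itself, fell (32 and 1 adjusted over the list alone), with a median of 0.49 (fry adjusted p = 0.0025, adjusted p = 0.67 with an estimated correlation). Rpn3 of the regulatory lid went from 85 ± 7.36 to 135 ± 15.8 CPM (0.67 ± 0.08, adjusted p = 1.9e-05), and Tbp-1 and Pros54 of the regulatory particle rose by 0.65 and 0.64. Complex I subunits moved the other way, with 31 of 34 lower and 34 adjusted over the list alone (median -0.33, fry adjusted p = 0.0014, adjusted p = 0.63 with an estimated correlation), among them CG15434 at -0.80 ± 0.11 and CG32230 at -0.64 ± 0.09. Of 30 sarcomere genes, 15 fell and none rose (16 adjusted over the list alone, median -0.26, fry adjusted p = 0.0055, adjusted p = 0.73 with an estimated correlation), led by the flight muscle troponin TpnC4 (-0.91 ± 0.10), the myosin light chain Mlc1 (-0.75 ± 0.09) and flightin, fln (-0.99 ± 0.14).

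Cytosolic heat shock genes and co-chaperones rose in 14 and fell in 3 of 25 members, and likewise in 14 and 3 adjusted over the list alone (median 0.25, fry adjusted p = 0.014, adjusted p = 0.78 with an estimated correlation). The small heat shock gene Hsp23 rose from 9.06 ± 4.27 to 107 ± 79.5 CPM (3.56 ± 0.46, adjusted p = 8.6e-05). Glutathione S-transferases and detoxifying P450s rose in 32 and fell in 7 of 59 members (35 and 8 adjusted over the list alone, fry adjusted p = 0.00071, adjusted p = 0.62 with an estimated correlation). GstD5 stood at 2.97 ± 0.25 and Cyp6g2 at -3.04 ± 0.26. Fat body genes rose in 10 and fell in 3 of 17, the same counts as adjusted over the list alone (fry adjusted p = 0.00019, adjusted p = 0.45 with an estimated correlation). The larval serum protein gene Lsp2 stood at 2.86 ± 0.36. Cytosolic peptidases, calpains and caspases rose in 9 and fell in 2 of 25 (9 and 3 adjusted over the list alone, fry adjusted p = 0.00066, adjusted p = 0.55 with an estimated correlation). The effector caspase Dcp-1 stood at 1.49 ± 0.11 and the calpain CalpB at 0.56 ± 0.06. Amyrel, an amylase-related gene, rose from 0.0974 ± 0.0734 to 22.6 ± 12.3 CPM (7.82 ± 0.58, adjusted p = 1.1e-06), and carbohydrate digestion genes rose in 11 and fell in 1 of 15 (11 and 1 adjusted over the list alone, fry adjusted p = 9.8e-06, adjusted p = 0.18 with an estimated correlation). Digestive proteases rose in 19 and fell in 2 of 31 (19 and 3 adjusted over the list alone, median 2.12, fry adjusted p = 0.00022, adjusted p = 0.45 with an estimated correlation). Their summed level was 8720 ± 3450 CPM against 10200 ± 451 with GFP RNAi and 8840 ± 592 with white RNAi. CG6277, a lipase-family gene, was at 10.1 CPM in GFP RNAi replicate 1 and at 0.0345 or less in the other 5 control thoraxes, and its log2 fold change was 10.22 ± 1.73. Jon65Ai rose by 9.89 ± 1.03, CG5767 by 9.13 ± 1.42, CG9468 by 9.12 ± 1.54 and CG9463 by 8.91 ± 1.41. Without GFP RNAi replicate 1 the values of these 5 genes were 13.49, 12.42, 13.18, 12.96 and 12.25, and that of Amyrel was 8.80. Without Prosbeta5 RNAi replicate 1 CG6277, CG5767, CG9468 and CG9463 stood at 9.57, 8.52, 8.44 and 7.88, and without white RNAi replicate 3 CG9463 stood at 9.88 and CG17475 at 12.03 in place of 11.05. CG17475, with 1 control count, gave a ratio of 2880 (95% counting interval 516 to 114000). The lowest genes were CG14075 (-3.88 ± 0.57), the adipokinetic hormone gene Akh (-3.75 ± 0.56), Cyp6g2, Lectin-galC1 (-2.94 ± 0.28), CG6432 (-2.92 ± 0.23) and CG13618 (-2.86 ± 0.34).

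The comparison of ND-75 RNAi thoraxes asks how the transcriptome responds when a complex I subunit is depleted. It called 1784 genes higher and 1605 lower, 437 and 337 of them by at least 2-fold. Heat shock genes and co-chaperones rose in 19 of 25 and fell in none (21 higher adjusted over the list alone, median 1.97, fry adjusted p = 4.7e-07, adjusted p = 0.16 with an estimated correlation). Hsp68 went from 33.3 ± 11.2 to 2030 ± 80.2 CPM (5.93 ± 0.39, adjusted p = 2.5e-07), Hsp26 from 47.9 ± 14.3 to 1310 ± 30 (4.79 ± 0.32), and the co-chaperone gene stv rose by 1.97 ± 0.11. This rise is not particular to ND-75 RNAi, since a like one, described below, was seen in thoraxes labelled Tm1 RNAi, where Tm1 was not lower. The other complex I subunits did not move together with ND75, with 8 higher, 1 lower (ND75) and 25 not called (7 and 1 adjusted over the list alone, fry adjusted p = 0.31 for one direction and 2.8e-12 for either, adjusted p = 0.92 with an estimated correlation), and ND23 rose by 0.34 ± 0.05. Mitochondrial chaperones and proteases rose in 6 of 14 and fell in none (6 adjusted over the list alone, fry adjusted p = 0.014, adjusted p = 0.91 with an estimated correlation). Hsp60 stood at 0.25 ± 0.04 and Hsc70-5 at 0.36 ± 0.07, where the median was 0.12 and the mean -0.38. Proteasome subunits fell in 11 of 34 (14 adjusted over the list alone, median -0.21), and as a list passed no threshold (fry adjusted p = 0.066). Of 11 tested genes for secreted signals of muscle stress, 4 rose and 5 fell (5 and 5 adjusted over the list alone, fry adjusted p = 0.29 for one direction and 1.2e-09 for either, adjusted p = 0.92 with an estimated correlation). Amyrel rose by 6.91 ± 0.59, or 7.89 without GFP RNAi replicate 1, the cytokine gene upd3 by 1.34 ± 0.30, and the insulin-binding factor gene ImpL2 fell from 208 ± 29.3 to 122 ± 17.6 CPM (-0.76 ± 0.14, adjusted p = 0.0011).

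Digestive proteases of the Jonah and trypsin families, whose near-identical members are uncertain, rose in 17 and fell in 5 of 31 in these thoraxes (17 and 8 adjusted over the list alone, median 1.33, fry adjusted p = 0.0016, adjusted p = 0.67 with an estimated correlation), although their summed level was 4400 ± 1200 CPM against 10200 ± 451 with GFP RNAi and 8840 ± 592 with white RNAi. Jon65Aii rose from 0.186 ± 0.345 to 26.2 ± 15.4 CPM. The largest rises were those of Jon65Ai at 10.21 ± 1.01, CG6277 at 9.08 ± 1.80 with the same single control library apart, CG33306 at 9.05 ± 0.87, CG10477 at 8.97 ± 0.86, Npc2d at 8.90 ± 0.98 and CG17475 at a ratio of 5770 (95% counting interval 1040 to 228000). Without GFP RNAi replicate 1 the first 5 stood at 12.74, 12.35, 11.31, 11.33 and 11.50. CG33306 stood at 10.04 without white RNAi replicate 2, Jon65Ai at 9.45 without ND-75 RNAi replicate 2, and CG17475 at 13.06 in place of 12.06 without white RNAi replicate 3. Among the lowest were the lysozyme gene LysE (-4.95 ± 0.45), uncertain as a member of a near-identical family, CG17192 (-4.39 ± 0.71), CG14075 (-4.37 ± 0.59), Akh (-4.31 ± 0.59), CG13618 (-4.27 ± 0.38) and CG7567 (-4.18 ± 0.77, or -4.83 without ND-75 RNAi replicate 1). LysE also differs between the controls, with -5.81 against GFP RNAi and -4.08 against white RNAi.

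In thoraxes labelled Tm1 RNAi, where Tm1 itself was not lower, the question is what else separates these libraries from the controls. There were 2368 genes higher and 2323 lower, 475 and 353 of them by at least 2-fold. Heat shock genes and co-chaperones were higher in 22 of 25 and lower in 1 (22 and 1 adjusted over the list alone, median 1.71, fry adjusted p = 1.3e-06, adjusted p = 0.17 with an estimated correlation). Hsp68 stood at 5.28 ± 0.38, stv at 1.71 ± 0.11 and the small heat shock gene l(2)efl at 1.38 ± 0.12. Haemocyte genes were lower in 8 of 12 and higher in 0 (9 lower and 1 higher adjusted over the list alone, median -0.86, fry adjusted p = 1.3e-06, adjusted p = 0.18 with an estimated correlation). The phagocytosis receptor gene eater went from 14.3 ± 2.65 to 5.1 ± 0.436 CPM (-1.47 ± 0.10), Hml was at -1.19 ± 0.10, and the collagen genes vkg and Cg25C were at -1.02 ± 0.08 and -0.85 ± 0.09. Glial genes were lower in 8 of 10 and higher in none (8 adjusted over the list alone, fry adjusted p = 1.1e-06, adjusted p = 0.24 with an estimated correlation). The gene axo stood at -0.49 ± 0.05 and the glutamine synthetase gene Gs2 at -0.32 ± 0.04. Complex I subunits were lower in 30 of 34 (33 adjusted over the list alone, median -0.29, fry adjusted p = 0.0015, adjusted p = 0.73 with an estimated correlation) and proteasome subunits in 24 of 34 (26 adjusted over the list alone, median -0.28, fry adjusted p = 0.016, adjusted p = 0.9 with an estimated correlation). Autophagy genes were lower in 8 of 24 and higher in none (8 adjusted over the list alone, fry adjusted p = 2.4e-06, adjusted p = 0.43 with an estimated correlation). Lamp1 stood at -0.49 ± 0.04 and Atg8a at -0.37 ± 0.05.

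Neuropeptide and hormone genes were higher in 15 of 24 members in these thoraxes and lower in 2 (16 and 2 adjusted over the list alone, median 0.59, fry adjusted p = 3.3e-07, adjusted p = 0.17 with an estimated correlation). The gene capa stood at 0.84 ± 0.06, Proct at 0.65 ± 0.05 and Akh, 1 of the lower members, at -4.81 ± 0.61. Antimicrobial and immune-induced peptide genes were higher in 21 of 33 and lower in 1 (21 and 2 adjusted over the list alone, fry adjusted p = 0.0074, adjusted p = 0.73 with an estimated correlation), with a median of 1.44, or 1.62 with groups at 0 counts set at their bound. Dpt went from 4.91 ± 2.82 to 87.4 ± 101 CPM (4.33 ± 0.64, adjusted p = 0.00018), and dro4 was lower (-1.49 ± 0.13). The P450 gene Cyp4g1, which acts in the oenocytes in making cuticular hydrocarbons, stood at 1300 ± 322 CPM against 17800 ± 2540 (-3.78 ± 0.29, adjusted p = 3.7e-07). The other lowest genes were Akh, CG14075 (-4.79 ± 0.61, or -5.54 without replicate 2 of the labelled group), CG6432 (-4.16 ± 0.25), v(2)k05816 (-4.13 ± 0.29) and CG13091 (-3.78 ± 0.40). Digestive proteases were higher in 19 of 31 and lower in none (19 adjusted over the list alone, median 2.44, fry adjusted p = 8.1e-05, adjusted p = 0.45 with an estimated correlation). Their sum was 10600 ± 1750 CPM against 10200 ± 451 with GFP RNAi and 8840 ± 592 with white RNAi. Other midgut genes summed to 2560 ± 412 against 7200 ± 125 and 8730 ± 135, although 9 of 18 were higher and 3 lower (9 and 3 adjusted over the list alone, median 1.23, fry adjusted p = 0.0042, adjusted p = 0.73 with an estimated correlation). The highest were Jon65Ai (10.38 ± 1.00), CG6277 (9.68 ± 1.76, 1 control library apart as above), CG5767 (9.20 ± 1.41), CG9468 (9.06 ± 1.54), CG9463 (8.59 ± 1.42) and CG17475, at a ratio of 4570 (95% counting interval 819 to 180000), and Amyrel was at 6.87 ± 0.59. Removal of GFP RNAi replicate 1 put Jon65Ai at 12.91, CG6277 at 12.94, CG5767 at 13.26, CG9468 at 12.89, CG9463 at 11.94 and Amyrel at 7.86. Removal of white RNAi replicate 3 put CG9463 at 9.58 and CG17475 at 12.71 in place of 11.72.

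TER94 RNAi thoraxes answer what follows when the ATPase that extracts ubiquitinated proteins is lowered. This comparison called 3291 genes higher and 3210 lower, 575 and 698 of them by at least 2-fold. With replicates 2 and 3 summed as 1 library, an alternative chosen after seeing the data because their counts lie closer together than those of any other pair, 5769 genes were called against 6501. These 2 libraries differed by a chi-square per degree of freedom of 1.76, against 9.29 or more for each other pair. Whether they hold the same RNA, which would leave this group with 2 samples behind its SDs and p-values, is not stated. Each of the 34 proteasome subunits rose, also adjusted over the list alone (median 1.06, fry adjusted p = 3.7e-07, adjusted p = 0.23 with an estimated correlation). Prosbeta5 went from 143 ± 8.58 to 546 ± 29.5 CPM (1.93 ± 0.05, adjusted p = 4.9e-13), Mov34 rose by 1.88 ± 0.08 and Prosalpha5 by 1.86 ± 0.10. Of 27 genes for folding and degradation at the endoplasmic reticulum, 7 rose and 10 fell, TER94 among them (7 and 10 adjusted over the list alone, fry adjusted p = 0.76 for one direction and 2.7e-15 for either, adjusted p = 0.99 with an estimated correlation). The 2 cofactors of VCP in this list moved apart, with Ufd1-like at 1.61 ± 0.09 and Npl4 at -1.50 ± 0.08. Each of the 34 complex I subunits fell, also adjusted over the list alone (median -0.76, fry adjusted p = 1.2e-06, adjusted p = 0.45 with an estimated correlation), with CG15434 falling from 128 ± 20.5 to 15 ± 0.729 CPM (-3.09 ± 0.13). Sarcomere genes rose in 4 and fell in 9 of 30 (3 and 9 adjusted over the list alone, median -0.05, fry adjusted p = 0.035, adjusted p = 0.92 with an estimated correlation), and the 2 largest falls were the flight muscle genes fln, from 361 ± 97.2 to 20.6 ± 1.91 CPM (-4.10 ± 0.16), and TpnC4 (-3.04 ± 0.12), while Act57B rose by 0.86 ± 0.12.

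Detoxification genes rose in 13 and fell in 27 of 59 in TER94 RNAi thoraxes (14 and 27 adjusted over the list alone, fry adjusted p = 0.019, adjusted p = 0.92 with an estimated correlation), with GstD9 rising from 45.2 ± 8.48 to 577 ± 72 CPM (3.69 ± 0.08) and Cyp6a17 near absent, at 0.675 ± 0.179 against 64.4 ± 5.33 (-6.57 ± 0.12). Lysosomal cathepsins and aspartic proteases rose in 1 and fell in 7 of 11 (1 and 7 adjusted over the list alone, fry adjusted p = 3.4e-07, adjusted p = 0.45 with an estimated correlation). CtsB1 stood at -0.39 ± 0.06. Immune serine proteases fell in 10 of 17 (10 adjusted over the list alone, fry adjusted p = 4.7e-06, adjusted p = 0.63 with an estimated correlation). The gene spirit stood at -0.90 ± 0.06 and the Spätzle-processing enzyme gene SPE at -0.53 ± 0.07. Serpins fell in 9 and rose in 2 of 26 (8 and 2 adjusted over the list alone, fry adjusted p = 0.0042, adjusted p = 0.92 with an estimated correlation). Spn77Ba stood at -0.73 ± 0.05. Glial genes fell in 9 of 10 (9 adjusted over the list alone, fry adjusted p = 7.6e-08, adjusted p = 0.26 with an estimated correlation). The gene nrv2 stood at -0.76 ± 0.06. Targets of ATF4 and the integrated stress response rose in 4 and fell in 2 of 17 (4 and 2 adjusted over the list alone, fry adjusted p = 0.0019, adjusted p = 0.83 with an estimated correlation). Gadd45 stood at 1.89 ± 0.14 and trbl at 0.67 ± 0.08. Digestive proteases rose in 13 and fell in 16 of 31 (13 and 16 adjusted over the list alone), with a median of -1.02, a mean of 0.50 and no call for the list (fry adjusted p = 0.6). Their sum reached 366 CPM in replicate 1 and 2060 and 2190 in replicates 2 and 3. The lowest genes were the lysozymes LysD (-7.92 ± 0.53), LysB (-7.68 ± 0.45) and LysC (-7.54 ± 0.47), uncertain as near-identical paralogs, then CG14075 (-7.58 ± 0.79) and Akh (-7.56 ± 0.79). The highest were Npc2d (7.24 ± 1.10), Jon65Ai (6.86 ± 1.40), CG17571 (6.82 ± 1.06), CG33306 (6.79 ± 0.96), CG7916 (6.59 ± 1.04) and CG17475, at a ratio of 1650 (95% counting interval 296 to 65300). Without GFP RNAi replicate 1 the first 5 of these stood at 9.83, 9.39, 10.05, 9.05 and 9.49, and Amyrel at 7.53. CG17571 and CG33306 stood at 7.44 and 7.77 without white RNAi replicate 2, and CG17475 at 11.24 in place of 10.26 without white RNAi replicate 3. Amyrel rose by 6.55 ± 0.60 and ImpL2 by 0.62 ± 0.14, and w went from 1.64 ± 0.136 to 76.6 ± 5.23 CPM (5.54 ± 0.15, adjusted p = 4.9e-13). The log2 fold change of w was -0.58, 0.05 and -0.58 in Prosbeta5, ND-75 and Tm1-labelled RNAi thoraxes, and 0.10 in TER94 RNAi heads. Whether the rise of w is a response to TER94 RNAi or a difference between the fly lines was not tested.

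Which thorax genes move the same way in all 4 RNAi groups was asked next. In the thorax, 296 genes were higher and 464 lower in all 4 groups. Independent lists of the same sizes would share 17.4 and 13.3, unchanged groups simulated against the same controls shared 4.6 and 0, and with the controls split between the comparisons the counts were 191 to 225 and 281 to 337. These checks address the sharing of controls only. None separates a response to the RNAi from any other difference between the flies of the 4 RNAi groups and the control flies. Ranked by the largest of their 4 adjusted p-values, the first 12 genes were all lower. The cuticle protein gene Cpr49Ab stood at 30.8 ± 5.88 CPM with GFP RNAi and 32.2 ± 8.86 with white RNAi, and at 0.229 ± 0.153, 0.194 ± 0.0561, 0.17 ± 0.051 and 0.252 ± 0.052 in Prosbeta5, ND-75, Tm1-labelled and TER94 RNAi thoraxes. The fatty acid elongase gene bond stood at -1.59, -2.01, -2.05 and -2.01 on the log2 scale in the same order, and differed between the controls as well (113 ± 13.3 and 154 ± 11.4 CPM, adjusted p = 0.011). CG31523, of the same elongase family, stood at -1.47, -1.80, -1.99 and -1.97, and the lipophorin receptor gene LpR1 at -1.01, -0.92, -1.33 and -1.55. The other 8 were CG3823, CG5065, gk, CG10479, CG1443, CG31832, CG13155 and CG2765. Photoreceptor genes fell in 1 to 3 of 16 members per group, passed no list test in any group (fry adjusted p from 0.076 to 0.23), and gave median log2 fold changes from -4.63 to -1.93. Their summed level was 1290 CPM in GFP RNAi replicate 3 and 1360 in white RNAi replicate 1, 846 in GFP RNAi replicate 2 and 369 to 438 in the other 3 control thoraxes, against 281 to 589 in the RNAi thoraxes.

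**Figure D2:**
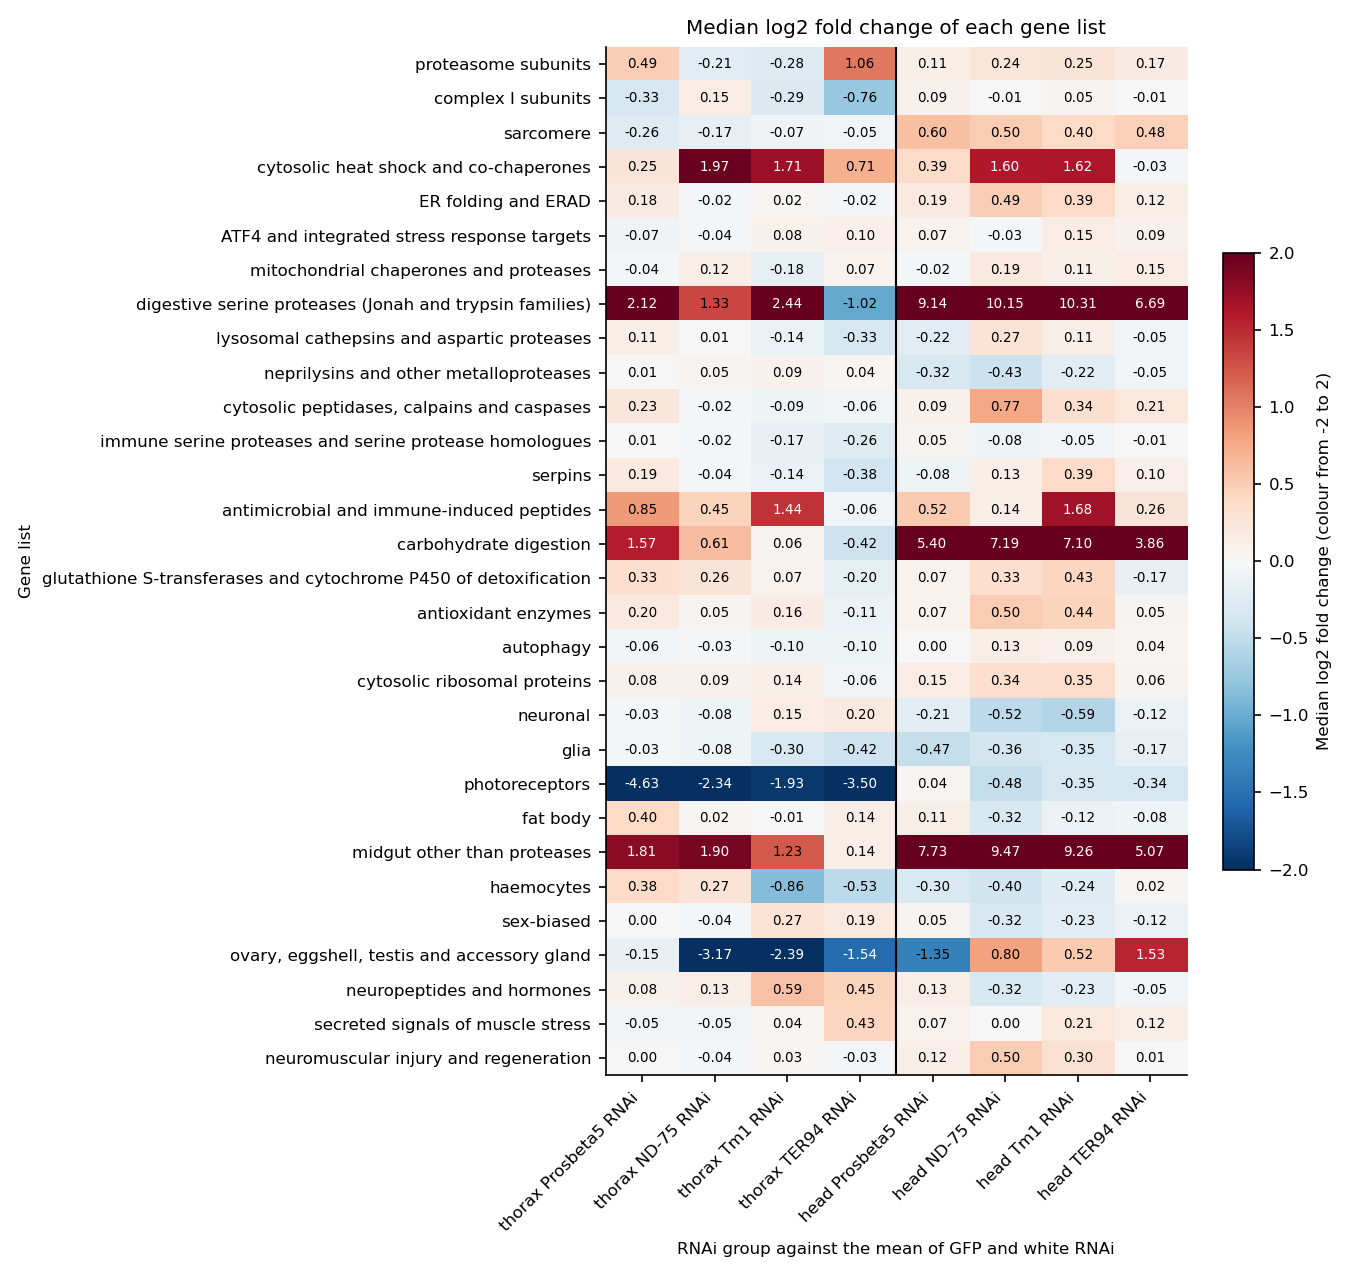
Median log2 fold change of the members of each gene list in the 4 RNAi groups of each tissue, printed in the cells and coloured from blue (lower) to red (higher) between -2 and 2. Proteasome subunits stand at 1.06 in TER94 RNAi thoraxes, and digestive proteases at 9.14 to 10.31 in the heads of 3 RNAi groups.

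In the head, the controls differed in 916 of 11338 genes, 450 higher and 466 lower in GFP RNAi. The count was 576 without GFP RNAi replicate 1, 530 without GFP RNAi replicate 2, 524 without white RNAi replicate 2 and 603 without white RNAi replicate 3, and without the expression filter the split was 469 higher and 323 lower. Of genes chosen after their values were seen, CG11313 stood at 0.0951 ± 0.0164 CPM with GFP RNAi and 92.5 ± 2.58 with white RNAi (-9.88, adjusted p = 5.6e-15), CG7900 at a log2 fold change of -2.73 (adjusted p = 3e-10), and Cyp4e3 at 142 ± 9.22 and 438 ± 23 (-1.62, adjusted p = 0.0011).

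The head comparisons ask what changes in the head when RNAi is directed at muscle, starting with Prosbeta5 RNAi, in whose heads 2669 genes were higher and 1614 lower, 735 and 152 of them by at least 2-fold. The share of higher genes depended on the method, with 62.3% in the fit reported, 51.2% with DESeq2 and 50.5% in a fit on the 9 compared libraries. Digestive proteases rose in 27 of 30 (28 adjusted over the list alone), with a median log2 fold change of 9.14 (fry adjusted p = 5.4e-08, adjusted p = 0.16 with an estimated correlation). Jon74E went from 0.716 ± 0.197 to 452 ± 200 CPM and betaTry from 1.9 ± 1.11 to 1640 ± 770, and both have close paralogs. Midgut genes other than proteases rose in 15 of 19 (16 adjusted over the list alone, median 7.73, fry adjusted p = 3e-07, adjusted p = 0.17 with an estimated correlation), such as the mucin gene Muc68D (0.268 ± 0.189 to 2220 ± 830 CPM). Carbohydrate digestion genes rose in 13 of 15 and fell in 2 (13 and 2 adjusted over the list alone, fry adjusted p = 8.2e-08, adjusted p = 0.11 with an estimated correlation). The amylase gene Amy-p stood at 6.57 ± 0.30 and the maltase genes Mal-A6 and Mal-A8 at 8.35 ± 0.41 and 9.75 ± 0.49. Sarcomere genes rose in 23 of 30 (24 adjusted over the list alone, median 0.60, fry adjusted p = 1.4e-06, adjusted p = 0.3 with an estimated correlation), led by the troponin C genes TpnC47D (0.459 ± 0.152 to 19.4 ± 2.73 CPM) and TpnC73F (3.32 ± 0.09).

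Glial genes fell in 9 of 10 in Prosbeta5 RNAi heads (9 adjusted over the list alone, median -0.47, fry adjusted p = 3.5e-08, adjusted p = 0.11 with an estimated correlation), with the astrocyte gene alrm at -2.55 ± 0.14, CG1732, a GABA transporter family gene, at -1.48 ± 0.08 and Gs2 at -0.53 ± 0.05. Neuronal genes fell in 10 of 16 (13 adjusted over the list alone, median -0.21, fry adjusted p = 0.0025, adjusted p = 0.74 with an estimated correlation), among them the sodium channel gene para (-0.86 ± 0.14). Neprilysins and other metalloproteases fell in 23 and rose in 2 of 36 (23 and 2 adjusted over the list alone, fry adjusted p = 2.6e-06, adjusted p = 0.18 with an estimated correlation). Nep4 stood at -0.65 ± 0.06. Heat shock genes rose in 15 of 25 (16 adjusted over the list alone, fry adjusted p = 0.00042, adjusted p = 0.75 with an estimated correlation). The gene l(2)efl stood at 2.06 ± 0.08 and Hsp27 at 3.40 ± 0.41, and the Hsp70 genes are near-identical copies. Ribosomal protein genes rose in 54 and fell in 1 of 87 (59 and 2 adjusted over the list alone, median 0.15, fry adjusted p = 0.0051, adjusted p = 0.92 with an estimated correlation), a count of 38 and 2 with DESeq2 size factors. The highest genes were CG34324 (0.226 ± 0.151 to 3100 ± 1160 CPM), CG31077, CG3906, CG14645 and CG14125, with log2 fold changes of 13.60 to 13.90, of which CG31077 went from 13.73 to 15.08 without GFP RNAi replicate 2. CG11672, with 2 control counts, gave a ratio of 9790 (95% counting interval 2710 to 80900), its log2 fold change going from 13.36 to 14.82 without white RNAi replicate 2. Besides alrm, the lowest were the odorant receptor gene Or92a (-3.23 ± 0.26), ImpE1 (-2.72 ± 0.23), the esterase gene Jhedup (-2.38 ± 0.17), CG13936 (-2.37 ± 0.23, -3.06 against GFP RNAi and -1.68 against white RNAi) and CG7509 (-2.11 ± 0.14). Amyrel was called (5.27 ± 1.46, adjusted p = 0.012), at 2.08 ± 2 CPM in Prosbeta5 RNAi heads, but not without their replicate 1 (4.21, adjusted p = 0.067). ImpL2 was not called (0.38 ± 0.15, adjusted p = 0.063), but was without replicate 3 of GFP RNAi (0.51) or of white RNAi (0.43).

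ND-75 RNAi heads, compared with the control heads on the same question, had 4196 genes higher and 3204 lower, 1327 and 151 of them by at least 2-fold. Digestive proteases rose in 28 of 30, also adjusted over the list alone (median 10.15, or 9.96 with groups at 0 counts set at their bound, fry adjusted p = 5.4e-08, adjusted p = 0.27 with an estimated correlation), from summed levels of 24.3 ± 24 and 11 ± 1.64 CPM in the controls to 22400 ± 4930. Midgut genes other than proteases rose in 17 of 19 (17 adjusted over the list alone, fry adjusted p = 5.4e-08, adjusted p = 0.3 with an estimated correlation). Muc68D stood at 6140 ± 1080 CPM against 0.268 ± 0.189. Cytosolic peptidases, calpains and caspases rose in 21 of 24 (21 adjusted over the list alone, median 0.77, fry adjusted p = 7.6e-06, adjusted p = 0.71 with an estimated correlation). The caspase genes decay and Damm went from 0.226 ± 0.207 to 90.5 ± 26.1 CPM and from 1.01 ± 0.0938 to 99.8 ± 34.6, and Dcp-1 rose by 1.69 ± 0.12. Antioxidant genes rose in 17 of 21 and fell in 1 (17 and 1 adjusted over the list alone, median 0.50, fry adjusted p = 5.4e-08, adjusted p = 0.39 with an estimated correlation). The metallothionein gene MtnC stood at 9.21 ± 0.48 and Jafrac2 at 1.00 ± 0.08. Both MtnC and decay were under 1 CPM in the control heads but present in the control thoraxes. With TER94 RNAi they were among 125 such genes that were higher in the head and lower in the thorax. Carried-over tissue, taken up below, is not excluded as their source in ND-75 RNAi heads. Genes for folding and degradation at the endoplasmic reticulum rose in 20 of 27 (20 adjusted over the list alone, median 0.49, fry adjusted p = 1.7e-06, adjusted p = 0.72 with an estimated correlation). The chaperone gene Hsc70-3 stood at 0.97 ± 0.08 and Xbp1 at 0.65 ± 0.04. Heat shock genes rose in 21 of 25 (21 adjusted over the list alone, fry adjusted p = 2.1e-07, adjusted p = 0.45 with an estimated correlation). The gene stv stood at 2.02 ± 0.12.

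Neuronal genes fell in 15 of 16 in ND-75 RNAi heads (15 adjusted over the list alone, median -0.52, fry adjusted p = 4e-06, adjusted p = 0.62 with an estimated correlation). VAChT stood at -0.75 ± 0.06, Gad1 at -0.64 ± 0.05 and Snap25 at -0.61 ± 0.06. Each of the 16 photoreceptor genes fell, also adjusted over the list alone (median -0.48, fry adjusted p = 1.3e-05, adjusted p = 0.63 with an estimated correlation), among them ninaC (-0.85 ± 0.07) and trp (-0.76 ± 0.09). The 16 genes summed to 55100, 70400 and 59800 CPM in replicates 1, 2 and 3, where digestive proteases summed to 24700, 16700 and 25700. How far gut transcripts in RNAi heads, taken up below, lower the CPM of head genes was not tested. Neuropeptide and hormone genes fell in 15 and rose in 6 of 27 (15 and 6 adjusted over the list alone, fry adjusted p = 0.043, adjusted p = 0.92 with an estimated correlation), and the median of -0.32 and the mean of 0.32 differ in sign, with Akh rising by 8.10 ± 0.23. The insulin-like peptide gene Ilp5 fell from 18.1 ± 1.55 to 9.35 ± 0.878 CPM (-0.95 ± 0.08). Ribosomal protein genes rose in 82 of 87, also adjusted over the list alone (median 0.34, fry adjusted p = 7.6e-06, adjusted p = 0.83 with an estimated correlation). RpS12 stood at 0.45 ± 0.04. Genes of neuromuscular injury and regeneration rose in 7 and fell in 1 of 11 (7 and 2 adjusted over the list alone, fry adjusted p = 8.1e-05, adjusted p = 0.91 with an estimated correlation). The integrin gene mys stood at 0.74 ± 0.08. Targets of ATF4 rose in 7 and fell in 4 of 17 (7 and 4 adjusted over the list alone, fry adjusted p = 0.00022, adjusted p = 0.92 with an estimated correlation), with a median of -0.03 and a mean of 0.31, the lactate dehydrogenase gene ImpL3 at 2.56 ± 0.17 and the translation repressor gene Thor at 1.41 ± 0.12. The highest genes were CG14125, CG31077, Muc68D, CG34324 and CG3906, at 14.13 to 15.11, and CG11672 at a ratio of 19300 (95% counting interval 5340 to 159000). CG31077 went from 14.91 to 16.26 without GFP RNAi replicate 2, and CG11672 from 14.35 to 15.80 without white RNAi replicate 2. The lowest were CG17018 (-2.44 ± 0.33), Osi2 (-1.80 ± 0.11), CG8757 (-1.74 ± 0.13), CG9377 (-1.66 ± 0.24), the odorant-binding gene Obp56e (-1.64 ± 0.08) and Cyp4e3 (-1.61 ± 0.23). All of these but Obp56e differ between the controls. The log2 fold changes against GFP and white RNAi were -3.11 and -1.77 for CG17018, -2.62 and -0.98 for Osi2, -2.51 and -0.97 for CG8757, -2.31 and -1.02 for CG9377, and -0.79 and -2.42 for Cyp4e3. The log2 fold change of w was -0.67 ± 0.07 (adjusted p = 7.3e-07), Amyrel rose by 6.15 ± 1.41, to 3.81 ± 3.54 CPM, or by 5.04 without replicate 1 of ND-75 RNAi, and ImpL2 was at 0.00 ± 0.15.

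Heads labelled Tm1 RNAi, in which Tm1 was higher, were compared with the control heads on the same question and had 4090 genes higher and 2750 lower, 1066 and 85 of them by at least 2-fold, or 3497 and 3205 with DESeq2 size factors. Digestive proteases were higher in 28 of 30, also adjusted over the list alone (median 10.31, fry adjusted p = 5.4e-08, adjusted p = 0.23 with an estimated correlation), at a summed 24600 ± 6230 CPM. Carbohydrate digestion genes were higher in 12 and lower in 2 of 15 (12 and 2 adjusted over the list alone, fry adjusted p = 6.4e-08, adjusted p = 0.17 with an estimated correlation). Amy-p stood at 3160 ± 1110 CPM against 29 ± 10.9. Lysosomal cathepsins and aspartic proteases were higher in 5 and lower in 1 of 10 (5 and 1 adjusted over the list alone, median 0.11, fry adjusted p = 5.5e-05, adjusted p = 0.92 with an estimated correlation). CtsB1 stood at 0.69 ± 0.05 and Bace, an aspartic protease gene near absent in the control heads, at 1320 ± 319 CPM against 0.731 ± 0.858. Serpins were higher in 11 and lower in 1 of 22 (11 and 1 adjusted over the list alone, fry adjusted p = 1.9e-05, adjusted p = 0.88 with an estimated correlation). Spn42Dc stood at 2.16 ± 0.14. Each of the 16 neuronal genes was lower, also adjusted over the list alone (median -0.59, fry adjusted p = 1.3e-06, adjusted p = 0.45 with an estimated correlation). The synaptotagmin gene Syt1 stood at -0.72 ± 0.06 and Rdl at -0.73 ± 0.06. Photoreceptor, glial and haemocyte genes were lower as well, in 12 of 16, 7 of 10 and 7 of 12 (14, 7 and 7 adjusted over the list alone), with 0, 1 and 0 higher. Their medians were -0.35, -0.35 and -0.24, and their fry adjusted p 0.00047, 8.9e-06 and 0.00099 (0.73, 0.54 and 0.73 with an estimated correlation). Ribosomal protein genes were higher in 84 of 87, also adjusted over the list alone (median 0.35, fry adjusted p = 8e-06, adjusted p = 0.78 with an estimated correlation), and heat shock genes in 20 of 25 (20 adjusted over the list alone, fry adjusted p = 1.2e-06, adjusted p = 0.48 with an estimated correlation). Hsp27 stood at 6.31 ± 0.43.

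Autophagy genes in heads labelled Tm1 RNAi were higher in 11 and lower in 3 of 24 (11 and 3 adjusted over the list alone, fry adjusted p = 1.4e-05, adjusted p = 0.92 with an estimated correlation). The gene ref(2)P, the p62 homologue, stood at 0.87 ± 0.07. The sex-biased list was higher in 1 and lower in 4 of 12 (1 and 4 adjusted over the list alone, fry adjusted p = 0.0031, adjusted p = 0.78 with an estimated correlation). The highest genes were CG14125, CG31077, Muc68D, CG34324, CG3906 and CG14645, at 13.81 to 14.83. CG31077 went from 14.30 to 15.65 without GFP RNAi replicate 2. Among the lowest, CG8245 went from 67.5 ± 2.65 to 24.6 ± 0.439 CPM (-1.46 ± 0.04) and CG31808 from 265 ± 16.8 to 98.6 ± 4.32 (-1.43 ± 0.05). CG34377 (-1.58 ± 0.15), CG43402 (-1.50 ± 0.19), CG7900 (-2.22 ± 0.11) and Cyp4e3 (-1.97 ± 0.24) also differ between the controls, with log2 fold changes of -0.96, -1, -0.86 and -1.16 against GFP RNAi and -2.21, -2, -3.59 and -2.78 against white RNAi. ImpL2 was at 0.37 ± 0.15 (adjusted p = 0.048), a call lost with DESeq2 size factors (0.31) and without replicate 1 or 2 of GFP RNAi (0.30 and 0.32), replicate 1 of white RNAi (0.28) or any replicate of the labelled group (0.38, 0.32 and 0.40). The gene w was at -0.49 ± 0.07. Amyrel, at 7.40 ± 11.4 CPM, was carried by replicate 3, without which its log2 fold change was 3.90 in place of 7.10.

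TER94 RNAi heads had 1973 genes higher and 1611 lower than the control heads, 584 and 94 of them by at least 2-fold, and 2380 in all without replicate 2. In a fit on the 9 compared libraries 1948 were higher and 2103 lower. Digestive proteases rose in 22 of 30 (25 adjusted over the list alone, median 6.69, fry adjusted p = 1.2e-06, adjusted p = 0.17 with an estimated correlation), at a summed 2300 ± 967 CPM, and CG6277, singled out after its values were seen, was at 0.379 CPM in replicate 2 against 30.1 and 47.1 in the other replicates. Midgut genes other than proteases rose in 13 of 19 (14 adjusted over the list alone, median 5.07, fry adjusted p = 3.4e-06, adjusted p = 0.18 with an estimated correlation). Muc68D stood at 1550 ± 695 CPM. Sarcomere genes rose in 25 of 30 (27 adjusted over the list alone, median 0.48, fry adjusted p = 3e-05, adjusted p = 0.45 with an estimated correlation), with the flight muscle actin gene Act88F going from 5.5 ± 3.14 to 24.1 ± 5.26 CPM (2.35 ± 0.12) and TpnC47D at 4.20 ± 0.12. Photoreceptor genes fell in 11 of 16 (13 adjusted over the list alone, median -0.34, fry adjusted p = 0.00035, adjusted p = 0.58 with an estimated correlation). The gene ninaC stood at -0.58 ± 0.07 and ninaA at -0.74 ± 0.09. Detoxification genes fell in 20 and rose in 9 of 60 (22 and 12 adjusted over the list alone, fry adjusted p = 0.0089, adjusted p = 0.73 with an estimated correlation), and Cyp6a17, at 1.05 ± 0.254 CPM against 43.5 ± 2.12, was the lowest gene. Proteasome subunits rose in 19 of 34 (21 adjusted over the list alone, median 0.17, fry adjusted p = 0.0089, adjusted p = 0.92 with an estimated correlation). Prosalpha1 stood at 0.70 ± 0.07 and Prosbeta5 at 0.46 ± 0.10. Genes of ovary, eggshell, testis and accessory gland were higher in 6 of 14 (6 adjusted over the list alone, fry adjusted p = 0.034, adjusted p = 0.92 with an estimated correlation), at low levels such as 2.36 CPM of Acp36DE against 0.0873. Of the heat shock genes 3 of 25 rose (2 adjusted over the list alone), with no call for the list (fry adjusted p = 0.41). The other lowest genes were squ (-2.72 ± 0.16), CG13022 (-2.42 ± 0.17), Cyp4e3 (-2.33 ± 0.24, -1.51 against GFP RNAi and -3.14 against white RNAi), Cyp309a2 (-2.28 ± 0.13) and the receptor gene Ir92a (-2.18 ± 0.13), and the highest besides Muc68D were CG14125, CG31077, CG34324, CG14645 and CG3906, at 11.99 to 12.87, with CG31077 going from 12.70 to 14.05 without GFP RNAi replicate 2. Amyrel (3.70 ± 1.59, adjusted p = 0.096), ImpL2 (0.40 ± 0.15, adjusted p = 0.056) and w (0.10 ± 0.07, adjusted p = 0.28) were not called, although ImpL2 was without replicate 3 of GFP RNAi (0.53) or of white RNAi (0.45).

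**Figure D3:**
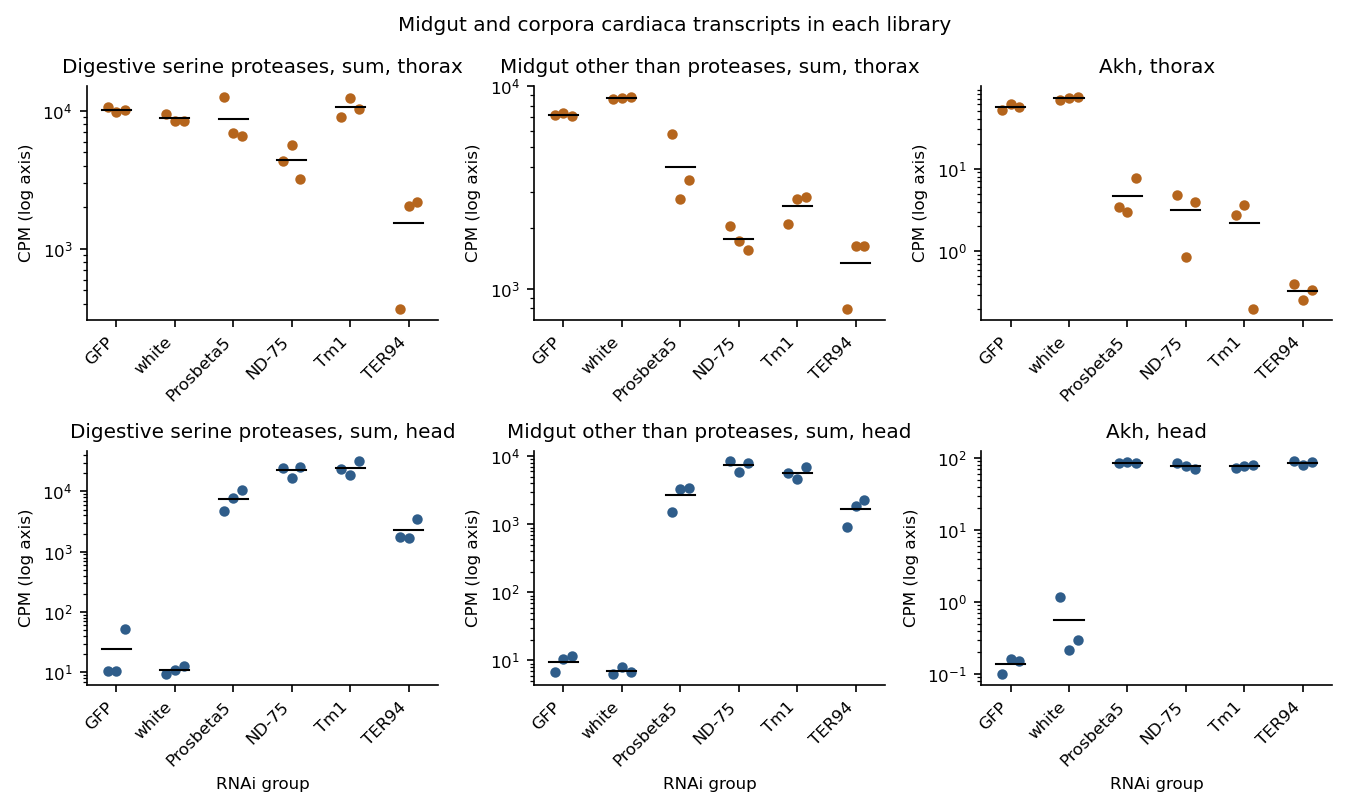
Summed CPM of digestive proteases, summed CPM of other midgut genes and CPM of Akh in each library, on log axes, with points for libraries and lines for group means, thorax in the upper panels and head in the lower ones. The control heads lie at 9.43 to 52 CPM of digestive proteases, and the RNAi heads average 2300 to 24600.

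Genes that moved together in the heads of all 4 RNAi groups numbered 998 higher and 436 lower, a share of higher genes of 69.6%, against 58.2% with DESeq2. Without genes under 1 CPM in the control heads, an alternative chosen after seeing the data, they numbered 577 and 494, or 53.9% higher, and the head counts of the 4 groups were 1912 higher and 1712 lower, 3219 and 3212, 3049 and 2984, and 1578 and 1526. Independent lists would share 62.0 and 15.7, simulated unchanged groups shared 2.1 and 0, and split controls gave 707 to 841 and 223 to 321. As in the thorax, these checks do not separate a response to the RNAi from any other difference between RNAi and control flies. Ranked by the largest of their 4 adjusted p-values, the first 12 genes were all higher. Akh stood at 0.139 ± 0.0335 CPM with GFP RNAi and 0.559 ± 0.525 with white RNAi, and at 86.6 ± 2.08, 77.6 ± 8.16, 76.4 ± 3.14 and 85.8 ± 5.73 in Prosbeta5, ND-75, Tm1-labelled and TER94 RNAi heads. CG14075 moved the same way, at 7.39, 7.33, 7.39 and 7.53 (8.03, 7.97, 8.02 and 8.16 without white RNAi replicate 1), and Cyp6g2 at 4.82, 4.64, 5.03 and 5.60. Both genes and Akh were among those that fell in the thorax. TpnC47D, TpnC73F, the villin-like gene qua, CG34220, CG40198, CG31823, CG6749, CG15213 and CG9411 complete the set. Of the genes higher in these heads, 540, 854, 676 and 496 had a mean under 1 CPM in the control heads, and they made up 2.04, 5.47, 4.62 and 0.754% of the RNAi libraries.

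Whether the head responds differently from the thorax under the same RNAi was tested in the joint fit. The responses differed in 3201 genes for Prosbeta5 RNAi, 6704 for ND-75 RNAi, 5881 for the libraries labelled Tm1 RNAi and 5619 for TER94 RNAi, and the head response was the higher one in 1380, 2334, 2241 and 2629 of them. For Prosbeta5 RNAi the split was 1757 higher and 1294 lower with DESeq2 size factors in place of 1380 and 1821. Genes higher in both tissues numbered 797, 1002, 1078 and 714, against 429, 662, 868 and 574 for independent lists, and genes higher in the head and lower in the thorax numbered 381, 550, 806 and 632, against 380, 589, 843 and 568. Those lower in both tissues numbered 361, 565, 645 and 577, against 222, 441, 554 and 449. Those lower in the head and higher in the thorax numbered 161, 227, 517 and 358, against 251, 495, 570 and 454. Akh differed by 11.90, 12.19, 12.68 and 15.74 on the log2 scale and bond by 3.39, 3.08, 3.20 and 2.92, and TpnC47D by 5.83 in the libraries labelled Tm1 RNAi and 4.66 with TER94 RNAi. The response of Prosbeta5 to its own RNAi was 0.82 higher in the head, that of ND75 2.02 higher and that of TER94 0.45 higher. Across genes, which are not independent replicates, head and thorax log2 fold changes had Pearson correlations of 0.384, 0.200, 0.284 and -0.128, and Spearman correlations of 0.233, 0.146, 0.120 and 0.045.

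**Figure D4:**
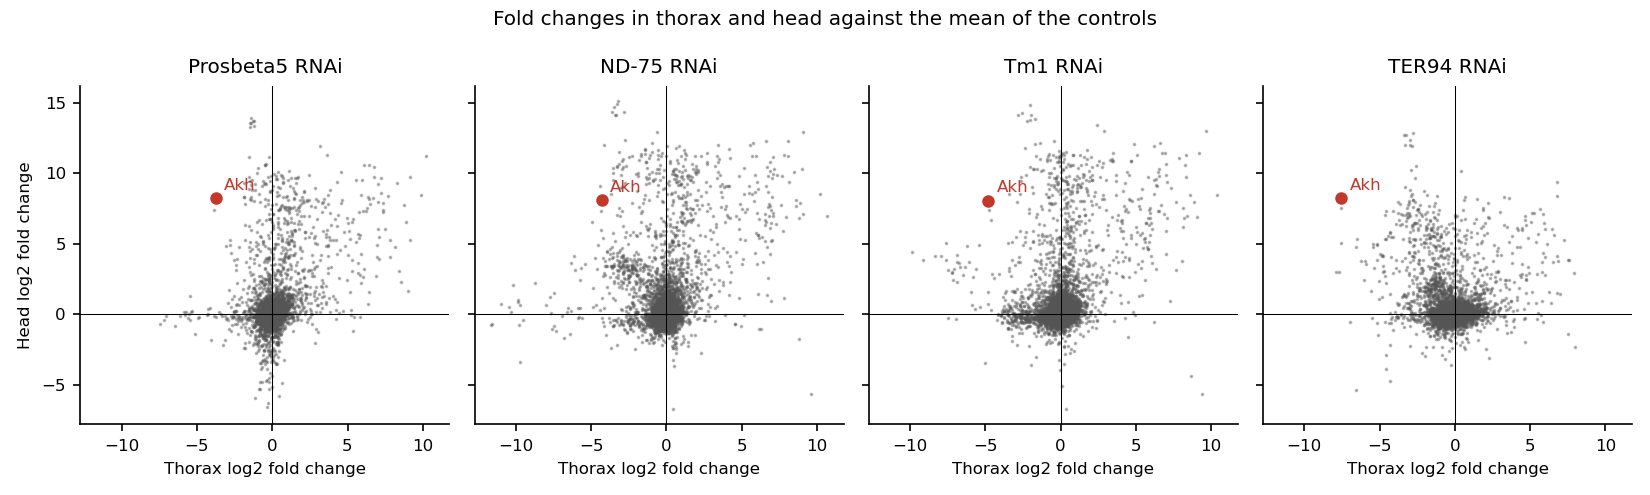
Log2 fold changes in the head against those in the thorax for each RNAi group, with 1 point per gene tested in both tissues and Akh marked in red. Akh lies at -7.56 in the thorax and 8.24 in the head of TER94 RNAi flies.

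How alike the 4 RNAi groups are was measured by the correlation of their log2 fold changes across genes, over 6 pairs per tissue that share the same controls. Pearson correlations ran from 0.48 to 0.90 in the thorax and from 0.79 to 0.93 in the head, against Pearson correlations of 0.18 to 0.23 for simulated unchanged groups. Spearman correlations ran from 0.27 to 0.53 and from 0.39 to 0.78. With 1 group set against GFP RNAi and the other against white RNAi, the Pearson correlations were 0.36 to 0.84 and 0.67 to 0.89. The covariances were 0.47 to 1.381 in the thorax and 1.311 to 2.891 in the head, against 0.017 to 0.032 simulated. Any difference between all RNAi flies and all control flies, whatever its source, would raise these values as well. ND-75 RNAi and the libraries labelled Tm1 RNAi were the closest pair in both tissues, at Pearson 0.90 in the thorax and 0.93 in the head. Because Tm1 was not lower in the libraries so labelled, changes shared by this pair cannot be assigned to the loss of ND75 from these data.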

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

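A result is listed here when the test of the head response minus the thorax response passed its threshold, which is what raised each of the following values. The tests of Akh, of the level of flight muscle transcripts and of library size for the gut transcripts, and each test of the other 2 patterns, were chosen after the result was seen, and the lists of gut identity and flight muscle genes after the first fold changes were seen. The responses differed in 3201 genes for Prosbeta5 RNAi, 6704 for ND-75 RNAi, 5881 for the libraries labelled Tm1 RNAi and 5619 for TER94 RNAi. In the same order of RNAi groups, the head minus thorax log2 fold change was 2.42, 2.92, 3.11 and 2.57 for CG31523, 3.02, 3.08, 2.92 and 3.51 for CG3823, and 3.07, 3.34, 3.11 and 2.57 for CG5065. It was 3.39, 3.08, 3.20 and 2.92 for bond and 2.24, 2.33, 2.55 and 2.45 for CG1443. Akh gave 11.90, 12.19, 12.68 and 15.74, CG14075 gave 11.17, 11.50, 11.97 and 15.05, and Cyp6g2 gave 7.77, 8.15, 8.37 and 7.59. CG40198 gave 6.30, 7.45, 6.65 and 7.25, CG31823 gave 5.56, 6.30, 6.31 and 5.88, and CG6749 gave 3.03, 2.60, 2.26 and 2.06. TpnC73F gave 3.73, 4.51, 3.67 and 3.31, CG9411 gave 6.51, 8.38, 7.27 and 6.76, and CG15213 gave 3.54, 4.92 and 3.3 in the first 3 groups. The value was 6.64 for CG31832 with Prosbeta5 RNAi, and 1.94 and 1.39 for CG2765 with Prosbeta5 and ND-75 RNAi. TpnC47D gave 5.83 in the libraries labelled Tm1 RNAi and 4.66 with TER94 RNAi, CG34220 gave 15.89 with ND-75 and 13.11 with TER94 RNAi, and qua gave 3.18 with ND-75 RNAi and 4.12 in the libraries labelled Tm1 RNAi. The targeted genes differed by 0.82 for Prosbeta5, 2.02 for ND75 and 0.45 for TER94, each under its own RNAi. ImpL2 differed by 0.56 with ND-75 RNAi, w by -0.93 with ND-75 RNAi and by -5.50 with TER94 RNAi, and Cyp6a17 by 1.15 with TER94 RNAi.

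Midgut transcripts in the heads of the 4 RNAi groups could stem from gut tissue carried over with the head, from induction of protease genes, or from library size. Gut identity genes outside digestion rose in every RNAi head group, with the smallest of the 4 medians at 2.43, and Akh, made by the corpora cardiaca beside the anterior gut, was lower in each thorax, at -3.75 where it moved least, while it rose in the heads. Most of the gut identity genes also rose in Prosbeta5, ND-75 and Tm1-labelled RNAi thoraxes, which moved tissue does not predict. In Prosbeta5, ND-75, Tm1-labelled and TER94 RNAi thoraxes, midgut genes other than proteases summed to 4000, 1770, 2560 and 1340 CPM. GFP and white RNAi thoraxes held 7200 and 8730, a difference that moved tissue predicts. Digestive proteases summed to 8720, 4400, 10600 and 1540 CPM, against 10200 and 8840. They were below both controls beyond the spread with ND-75 and TER94 RNAi only. Digestive proteases and other midgut genes varied together across the 12 RNAi head libraries around their group means (Pearson 0.802, Spearman 0.699, exact permutation p = 0.0062 and 0.016, Pearson 0.713 without the 2 farthest libraries), although 3 of 100 random pairs of lists correlated as strongly. Proteases induced alone are excluded by the midgut list without proteases, whose smallest median was 5.07, and library size by a largest ratio of 1.65 between head libraries. The flight muscle list had medians of 1.47, 1.03, 0.39 and 2.65 in the 4 head groups, with errors of 0.19, 0.38, 0.36 and 0.4, so some carried-over muscle is not excluded. By level, the share of their thorax level that the gut lists reached was set against that of any of 4 flight muscle genes. The ratio was 32.7 with ND-75 RNAi and 19.7 in the heads labelled Tm1 RNAi, which argues against flight muscle as the source there. With Prosbeta5 RNAi, at 2.78, and TER94 RNAi, at 1.64, flight muscle is left open. These ratios are taken between single libraries without a measured spread, and the RNAi thoraxes they rest on held less of the midgut genes other than proteases than the controls. A different division of tissue at the neck is left open by ratios of thorax shares of 0.75, 2.13, 0.876 and 2.67. The Fisher p were 0.25, 3.9e-07, 0.5 and 1.1e-35 in the same order. The ratios of ND-75 and TER94 RNAi go with such a division, and the 2 ratios under 1 do not. The genes behind these ratios went both ways in the thorax (17, 47, 30 and 125 lower, which moved tissue predicts, and 67, 60, 56 and 13 higher, which it does not). Carried-over gut may thus account for the rise, while a gut-wide induction was not excluded.

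CG11313 and Cyp6a17 were near absent in whole groups of libraries in both tissues, and y in the thorax, which could reflect variants of the fly lines, responses to the RNAi, or read assignment. CG11313 was low with GFP RNAi, TER94 RNAi and in the libraries labelled Tm1 RNAi, y with white, Prosbeta5, ND-75 and TER94 RNAi, and Cyp6a17 with TER94 RNAi. The lowest library of the high groups exceeded the highest of the low groups by a factor of at least 1.98, reached by y in the head, where no library held more than 2.51 CPM and the scaled ratio was 2.12. Apart from y in the head, the factor was at least 148 for CG11313 and 29.2 for Cyp6a17 in both tissues, and 110 for y in the thorax. A line variant is possible and left open. A response to the 4 targets is excluded for CG11313 and y in the thorax by the ratio of at least 279 between the 2 control groups there, and left open for Cyp6a17, with a ratio of 1.11. Reads of Cyp6a17 given to its neighbour Cyp6a23, a gene chosen after its values were seen, are left open. Cyp6a23 gained -45.5% of the loss in the thorax and 71.7% in the head. Its net change cannot separate reads gained from a change in its own expression.

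Tm1 was not lower in the thorax libraries labelled Tm1 RNAi, for which exchanged labels or a GFP RNAi genotype under another label could account. Exchanged labels would leave Tm1 low in another RNAi group if its RNAi lowers the transcript, and the lowest log2 fold change of Tm1 in the other thoraxes was -0.11. Prosbeta5, ND75 and TER94 stood at -1.06, -2.57 and -0.61 in the thoraxes of their own label. In those labelled Tm1 RNAi they stood at -0.47, -0.21 and -0.33. These values argue against an exchange with the other RNAi groups. Between the thoraxes labelled Tm1 RNAi and those of GFP RNAi 3990 genes were called, against 1409 between the controls. They include what sets all 4 RNAi groups apart from the controls. Against GFP RNAi alone, 794 thorax genes were called in the same direction in all 4 groups, so most of the 3990 lie outside that shared set. That set leaves out changes shared with fewer groups. Against the pooled controls, 1300 higher and 1550 lower genes were called both in these thoraxes and in those of TER94 RNAi. How many of the 3990 are particular to these libraries is thus not shown. However, CG11313 and y in the thoraxes labelled Tm1 RNAi were within 1.72 and 1.02 times the GFP RNAi level but 639 and 272 times from that of white RNAi. A GFP RNAi genotype is thus left open, with the levels of CG11313 and y for it and a count of genes that does not decide. Compensation by the remaining transcript, or depletion that the RNA level does not show, was not tested.

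Whether chance can be excluded was examined by calling genes in other splits into groups of the same sizes, in fits on the compared libraries that take the 2 control genotypes as 1 group, unlike the fits reported. In each of the 4 thorax and 4 head comparisons, 1 of 84 splits, the real one, reached the real count. The real and the highest other counts were 2108 and 757, 2276 and 643, 3463 and 492, and 5552 and 398 in the thorax, and 3658 and 521, 6664 and 254, 5766 and 230, and 3087 and 588 in the head, in the order used above. For GFP against white RNAi 10 splits are too few to exclude chance, with 1131 against 0 in the thorax and 1234 against 4 in the head. For genes called in all 4 groups, 1 of 100 splits reached the real count, 620 against 0 in the thorax and 1258 against 0 in the head. For the difference between tissues it was also 1 of 100, with 2448 against 42, 5936 against 5433, 5081 against 3325 and 5092 against 1113, and why single other splits called so many genes for ND-75 RNAi and the libraries labelled Tm1 RNAi was not examined.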

How the results depend on the processing

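Leaving out 1 library at a time moved 7 of 84 counts of changed genes by more than 1.5 times. For GFP against white RNAi the leave-one-out counts ran from 524 to 698 in the head, against 916, and from 781 to 1196 in the thorax, against 1409. For TER94 RNAi heads they ran from 2380, without replicate 2, to 3600, against 3584. The log2 fold change of Tm1 in the thoraxes labelled Tm1 RNAi ran from 0.04 to 0.13 and passed the threshold upward without GFP RNAi replicate 3. Gene set tests fell from 144 calls with fry to 0 with camera, which compares a list with other genes and estimates the correlation between genes. The cause of these shifts was not tested. Of the single named genes, 1956 of 1980 values kept direction and call with a library left out (18 weaker, 6 stronger), and 1612 of 1629 with another setting (10 weaker, 7 stronger), and none was reversed. Against a single control, up to 8 genes called in both analyses turned direction, a number reached by ND-75 RNAi against white RNAi in each tissue. The balance of higher and lower genes turned in 25 of 303 recounts. These were 6 for the thoraxes labelled Tm1 RNAi (2368 and 2323, as far as 2290 and 2523 with the Wald test), 7 for TER94 RNAi thoraxes (3291 and 3210, as far as 3174 and 3333 with the Wald test) and 3 for the tissue difference of Prosbeta5 RNAi (1380 and 1821, against 1757 and 1294 with DESeq2 size factors, 1815 and 1396 with the Wald test and 1555 and 1435 without the filter). The others were 1 for TER94 RNAi heads (1973 and 1611, against 1948 and 2103 in the fit on the 9 compared libraries), and 6 in the head and 2 in the thorax for GFP against white RNAi. The 72 counts of changed genes and 25 counts of tissue differences stayed within 1.5 times under every other setting. Whether libraries of the same replicate number form pairs is not stated, and a replicate block gave 3268 genes for Prosbeta5 RNAi thoraxes against 3414, 4235 for their heads against 4283, and 742 and 1414 genes called in all 4 groups against 760 and 1434. Of alternatives chosen after seeing the data, summing TER94 RNAi thorax replicates 2 and 3 gave 5769 genes against 6501, and leaving out genes under 1 CPM in the control heads gave 3624, 6431, 6033 and 3104 in the 4 head comparisons and 1071 in all 4.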

Other observations

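Several gene groups outside the main descriptions moved as well. The lists of gut identity, indirect flight muscle and corpora cardiaca genes were chosen after seeing the data. Gut identity genes rose in 5, 6 and 5 of 7 in Prosbeta5, ND-75 and Tm1-labelled thoraxes, and in 2 with 3 lower in TER94 RNAi thoraxes. In the heads 5, 7, 7 and 5 of 7 rose, with medians of 2.43, 5.36, 5.42 and 2.99 (fry adjusted p of 1.9e-07 to 7.9e-05, adjusted p = 0.12 to 0.14 with an estimated correlation). Of 4 indirect flight muscle genes, 3 fell with Prosbeta5 RNAi, 4 were lower in the thoraxes labelled Tm1 RNAi and 3 fell with TER94 RNAi, with medians of -0.79, -1.02 and -1.98, and in the heads of Prosbeta5 and ND-75 RNAi and those labelled Tm1 RNAi 2, 2 and 2 were higher and none lower, with medians of 1.47, 1.03 and 0.39 (fry adjusted p = 3e-05, 9.3e-05 and 0.00021, adjusted p = 0.18, 0.49 and 0.49 with an estimated correlation). In TER94 RNAi heads 4 rose, with a median of 2.65 (fry adjusted p = 4.2e-05, adjusted p = 0.12 with an estimated correlation). In ND-75 RNAi thoraxes 1 rose and 1 fell. The corpora cardiaca list has 1 gene, Akh, described in the report. Haemocyte genes fell in 8 of 12 in TER94 RNAi thoraxes (median -0.53, fry adjusted p = 1.3e-05, adjusted p = 0.63 with an estimated correlation) and rose in 8 with Prosbeta5 RNAi (median 0.38, fry adjusted p = 0.00023, adjusted p = 0.53 with an estimated correlation).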
